A study of Ipomoea batatas with 18 samples.

How the data were processed

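RNA was measured in roots of 2 sweetpotato (Ipomoea batatas) cultivars, the high-starch Chuanshu 218 and the low-starch 15-94, at 30, 65 and 100 days of age. The plants stood in greenhouse pots under natural light. Per the labels' protocols, total RNA was extracted with Trizol, freed of DNA with a TURBO DNA-free kit and made into TruSeq stranded mRNA libraries. There were 18 libraries in 6 groups of 3. The labels do not say which plant gave which library, so the p-values measure the spread between these libraries, which may be partly technical.

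The authors deposited 1 table of FPKM values (fragments scaled by transcript length and by the mapped fragments of the library) for 46840 unigenes, which are transcripts from a de novo assembly per the labels. The submitters' processing notes name edgeR, with no role and no version. The assembler, the aligner, the counter and any scaling between libraries are not given in the sources used here. The FPKM sum per library ran from 731156 to 1471677, and each of the 18 value columns matched 1 library by its label.

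The table does not pair unigene IDs with gene names. The gene table of reference assembly IBA_r1.0 was searched for them, and 0 IDs matched. The gene lists fixed beforehand (starch, sugar, hormone, cell wall and other pathways) could therefore not be tested, and unigenes are described by cultivar, age and abundance. At most 2 IDs higher and 2 lower in the high-starch cultivar are named. The rule, fixed before the data were examined, took the called unigene with the largest difference in each direction, averaged over the ages, among those with a mean of at least 10 FPKM in the higher cultivar and no overlap between the cultivars' libraries. The same rule applied to the change from 30 to 65 days in the high-starch cultivar found 0 unigenes. The unigene ranked next in each direction was added after the values were seen.

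FPKM values are not counts, so no count model was used. Unigenes with at least 1 FPKM in at least 3 libraries (32529) were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with 6 groups, 12 residual degrees of freedom and an eBayes trend. A call needed a Benjamini-Hochberg adjusted p under 0.05 within its comparison and a difference of at least 2-fold. Differences on this scale understate the change of unigenes of low abundance. The 10 comparisons were the cultivar difference at each age and averaged over ages, the changes between successive ages in each cultivar, and the 2 interactions. Called unigenes were compared between ages by overlap. Unigenes with at least 1 FPKM in all 9 libraries of 1 cultivar and 0 in all 9 of the other were counted. The share of variance due to cultivar or age was tested by permutation, which was added after the data were seen.

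The number of reads per library is not given. Low FPKM values lie on steps set by what 1 read is worth, and the ratio of these steps between libraries gives relative depth, provided that the FPKM values were not scaled further between libraries. Pairwise ratios were within 0.05 (log2) of the fitted values for 97.4% of library pairs, and on simulated data the largest error was 0.0008. The absolute depth remains unknown, so no floor or counting interval is given. The limma step was tested on simulated data with 50 changed unigenes per fold size among 32529. The changed unigenes were drawn from those averaging above about 5 FPKM on the log2 scale. Recovery needed an adjusted p under 0.05 and the right sign, without the 2-fold limit of a call. With that limit the shares can only be equal or lower. For the averaged cultivar comparison, 34% of log2 changes of 1 and 84% of log2 changes of 2 were recovered. For the change from 30 to 65 days in the high-starch cultivar the shares were 0% and 26%, and for the interaction from 30 to 65 days they were 0% and 2%. The limit on the adjusted p is stricter where few unigenes change. These shares therefore hold for changes as few as those simulated and would be higher with more.

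The alternatives planned beforehand were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, no eBayes trend, fits of only the libraries compared, a replicate block, leaving out each library, other limits for the overlaps and zero listings, and unit variance for the separation of libraries. Array weights, relative depth as a covariate, the omission of 2 sets of libraries, separate fits for the sharing between ages and comparisons of 30 with 100 days were chosen after seeing the data. Permutations and figures used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.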

Results

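Root transcriptomes of the high-starch sweetpotato cultivar Chuanshu 218 and the low-starch cultivar 15-94 were compared at 30, 65 and 100 days, with 3 libraries per cultivar and age. Between 24300 and 36939 of the 46840 unigenes had an FPKM above 0 in a library. High-starch libraries held 32946 ± 2491 such unigenes (SD, n = 9) and low-starch libraries 28197 ± 2348 (SD, n = 9; exact permutation within age, two-sided p = 0.0025). The relative value of 1 read in FPKM also differed. It was set to 0 (log2) in the library with the smallest value, high-starch 30 d replicate 2. On this scale it averaged 0.50 ± 0.38 (log2, SD, n = 9) in the high-starch and 1.13 ± 0.40 in the low-starch libraries (exact permutation p = 0.003). This corresponds to shallower low-starch libraries if the FPKM values were not scaled further between libraries. Whether they were is not given in the sources used here.

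Cultivar separated the libraries more than age did. It accounted for 31.0% of the variance of log2(FPKM + 1), with a permutation p of 0.00025, the smallest the 8000 exact relabellings within age can give. Age within cultivar accounted for 19.5%, with a permutation p of 0.22 from 100000 resamples. Profiles of libraries from the same group had a mean correlation across unigenes of 0.878 (18 pairs). Libraries of the same cultivar at other ages had 0.870 (54 pairs), and libraries of the other cultivar 0.785 (81 pairs). Unigenes are not independent replicates, and these correlations describe the profiles. With unit variance per unigene, cultivar accounted for 21.9% of the variance.

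**Figure D1:**
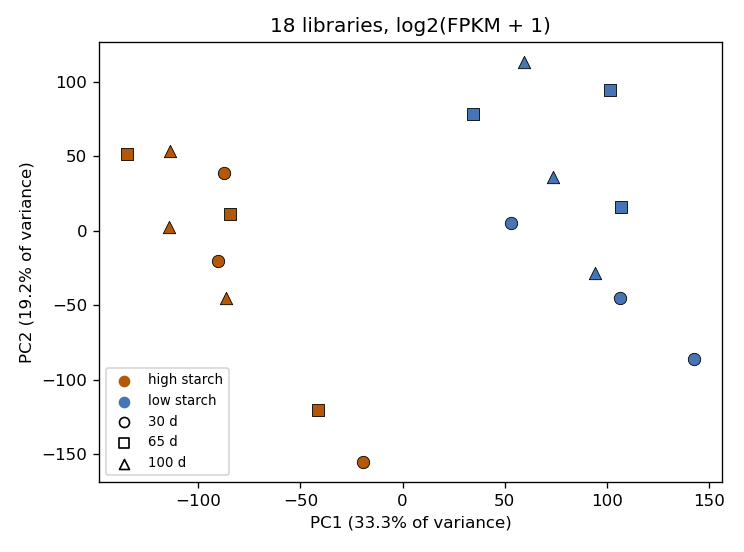
Principal components of log2(FPKM + 1) over 32529 unigenes, with 1 point per library, colour for cultivar and shape for age; the axes are component scores. The first component (33.3% of variance) parts the cultivars, and the second (19.2%) spreads libraries of the same group.

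The second component was compared with the value of 1 read, the measure of relative depth, within each cultivar. Its correlation with the log2 value of 1 read was r = -0.82 in the 9 high-starch libraries (permutation p = 0.0066, adjusted p = 0.0099 over 6 relations; Spearman rho = -0.65, permutation p = 0.067). Without the 2 libraries farthest from the median it was r = -0.62. In the 9 low-starch libraries it was r = -0.71 (permutation p = 0.027, adjusted p = 0.027; rho = -0.57, permutation p = 0.12), and without the 2 farthest libraries it was r = -0.07, so there the relation rests on those libraries. They are low-starch 30 d replicates 1 and 3, so depth and age go together in them.

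The cultivar comparison asks which transcripts differ between roots of the high-starch and the low-starch cultivar. Starch class and cultivar coincide here, so no difference can be assigned to starch. Averaged over the 3 ages, 3619 unigenes were higher and 2345 lower in the high-starch cultivar (limma, adjusted p under 0.05 and at least 2-fold). The median absolute difference of the called unigenes was 1.51 (log2), and 538 differed at least 8-fold. With a filter at 5 FPKM, which tests fewer unigenes, the calls were 2132 and 1828. The files do not pair these IDs with gene names. The higher unigene with the largest difference on the log2(FPKM + 1) scale, Iba_32651, had 778.7 ± 469.1 FPKM in the high-starch cultivar and 3.01 ± 2.50 in the low-starch cultivar (SD, n = 9 each), a log2 difference of 7.62 (SE 0.36, limma adjusted p = 5.37e-11). The lower unigene with the largest difference on this scale, Iba_24790, had 0.63 ± 0.53 FPKM in the high-starch and 557.3 ± 283.3 FPKM in the low-starch cultivar (SD, n = 9 each), a log2 difference of -8.37 (SE 0.26, limma adjusted p = 2.18e-12). Next in rank, an order that turned in 8 of 31 other settings for the higher and 2 for the lower pair, and chosen after their values were seen, were Iba_33414, with 306.2 ± 210.4 against 0.42 ± 0.35 FPKM, and Iba_34341, with 3.52 ± 3.23 against 1131 ± 760 FPKM (SD, n = 9 each). All 9 libraries of the higher cultivar lay above all 9 of the other for these 4 unigenes, which the choice required. Counting these, 333 higher and 412 lower unigenes met the same conditions of level and separation.

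**Figure D2:**
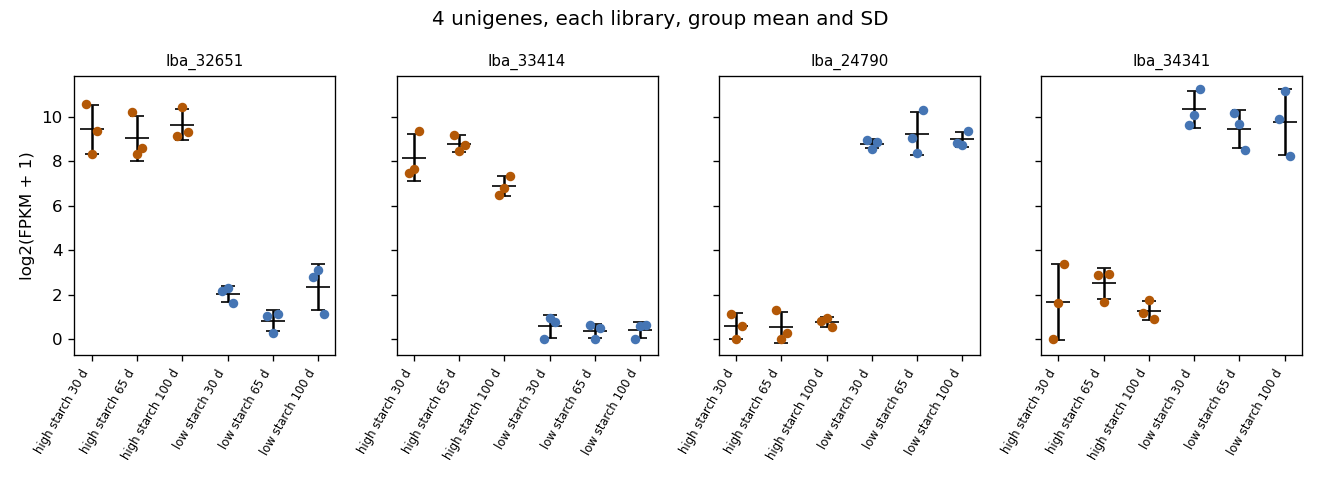
FPKM of 4 unigenes as log2(FPKM + 1) in each library by cultivar and age; points are libraries, the horizontal marks group means and the bars SD (n = 3). Iba_32651 and Iba_33414 lie higher in the high-starch cultivar and Iba_24790 and Iba_34341 higher in the low-starch cultivar at all 3 ages.

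The direction of the averaged difference varied with abundance. Among unigenes with a mean under 5 FPKM, 2277 were higher and 995 lower in the high-starch cultivar, 69.6% higher. From 5 to 20 FPKM the numbers were 953 and 737, and at 50 FPKM and over they were 132 and 288, 31.4% higher. Among the 100 most abundant unigenes, 4 were higher and 12 lower. Quantile normalization gave 2692 higher and 2736 lower over all unigenes, 49.6% against 60.7% as deposited, with 51.8% higher under 5 FPKM and 41.4% at 50 FPKM and over. It also moved the median log2 difference of all unigenes from 0.17 to 0.05. Median-of-ratios scaling left the pattern almost as deposited, with 69.2% higher under 5 FPKM and 30.7% at 50 FPKM and over. With relative depth as a covariate, added after seeing the data, 61.3% of calls were higher, 64.1% under 5 FPKM and 63.5% at 50 FPKM and over, so the direction among the abundant unigenes turned.

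**Figure D3:**
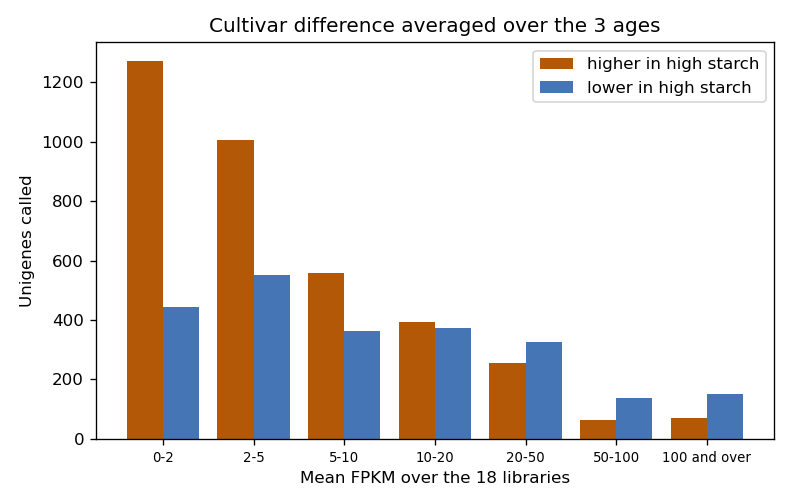
Number of unigenes called higher or lower in the high-starch cultivar, averaged over the 3 ages, by mean FPKM over the 18 libraries; bars start at 0. Higher unigenes outnumber lower ones 1271 to 444 under 2 FPKM, and lower ones outnumber higher ones 151 to 70 at 100 FPKM and over. As stated in the text, the pattern stayed under median-of-ratios scaling and weakened under quantile normalization. The direction among abundant unigenes turned with the depth covariate.

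At 30 days, 1383 unigenes were higher and 943 lower in the high-starch cultivar by limma. Iba_32651 had 838.3 ± 625.8 against 3.21 ± 0.99 FPKM and Iba_24790 had 0.58 ± 0.62 against 447.2 ± 61.3 FPKM (SD, n = 3 each). Under quantile normalization the calls were 1018 and 1030, 49.7% against 59.5% higher. A fit of only the 6 libraries compared called 483 and 409, relative depth as a covariate 831 and 459, array weights 3403 and 2236, and a filter at 5 FPKM 880 and 830.

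At 65 days, 2012 unigenes were higher and 1311 lower. Iba_32651 had 626.7 ± 473.6 against 0.85 ± 0.55 FPKM and Iba_24790 had 0.58 ± 0.81 against 709.4 ± 495.6 FPKM (SD, n = 3 each). Without low-starch 65 d replicate 3 the calls were 1231 and 775, and a fit of only the libraries compared called 1043 and 762. Quantile normalization called 1666 and 1552, 51.8% against 60.5% higher, and a filter at 5 FPKM 1169 and 989.

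At 100 days, 1694 unigenes were higher and 1280 lower. Iba_32651 had 871.0 ± 459.9 against 4.95 ± 3.30 FPKM and Iba_24790 had 0.72 ± 0.25 against 515.4 ± 127.0 FPKM (SD, n = 3 each). A fit of only the libraries compared called 2512 and 1720, more than with all 18, unlike at 30 and 65 days. Quantile normalization called 1305 and 1495, 46.6% against 57.0% higher, relative depth as a covariate 1122 and 801, and array weights 5404 and 3686. A filter at 5 FPKM called 987 and 1135, 46.5% higher, so under this filter, as under quantile normalization, lower calls outnumbered higher ones. Several single libraries moved the counts by over 1.5 times: higher calls numbered 934, 1086, 951, 1024 and 1084 without high-starch replicate 1 or 3 or low-starch replicate 1, 2 or 3, and lower calls 663, 794, 839 and 806 without high-starch replicate 1, 2 or 3 or low-starch replicate 1.

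Cultivar calls were shared between ages more often than random lists would share them, though most were not made at all 3 ages. Called higher at all 3 ages were 738 unigenes, and called lower at all 3 were 535, while 2996 and 2049 were called at any age. Between 30 and 65 days, 978 higher and 637 lower calls were shared, where random lists of these lengths would share 85.5 and 38.0. Between 65 and 100 days, 1009 and 779 were shared, where random lists would share 104.8 and 51.6, and between 30 and 100 days 844 and 604, against 72.0 and 37.1. These comparisons share 1 variance estimate from all 18 libraries, so the lists are not independent. In 3 separate fits with no library in common, added after seeing the data, 366 and 292 calls were shared between 30 and 65 days (15.5 and 9.58 for random lists), 744 and 572 between 65 and 100 days (80.5 and 40.3) and 406 and 326 between 30 and 100 days (37.3 and 21.6). At all 3 ages the separate fits called 334 higher and 276 lower, fewer than the 738 and 535 above, while 2856 and 1977 were called at any age. Random lists take no account of abundance, so the values for random lists are reference values only. Only 1 unigene was called in opposite directions, lower at 65 and higher at 100 days, and 0 in the separate fits. Across unigenes the log2 differences at 30 and 65 days had r = 0.687, a value over genes, which are not independent replicates.

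Some transcripts were listed in 1 cultivar only. At 1 FPKM or more in all 9 high-starch libraries and 0 in all 9 low-starch libraries were 190 unigenes, with a median of the mean levels of 4.81 FPKM, and 107 showed the opposite listing, with a median of 7.79 FPKM. At a minimum of 5 FPKM the numbers were 20 and 23. A listed 0 is not proof of absence, and 1 read was worth more FPKM in the low-starch libraries.

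The age comparisons ask how root transcripts change within a cultivar between successive ages. No unigene passed in any of the 4. In the high-starch cultivar, 832 unigenes had an unadjusted limma p under 0.05 from 30 to 65 days and 2420 from 65 to 100 days, and in the low-starch cultivar 4001 and 1083, where 1626 of 32529 would be reached by chance. The smallest adjusted p values were 1, 0.061, 0.054 and 0.10. Iba_32651 had a log2 difference of -0.39 (SE 0.62) from 30 to 65 days in the high-starch cultivar. In the simulation 26% of log2 changes of 2 and 58% of log2 changes of 3 were recovered for that comparison by adjusted p alone. If as few unigenes changed as in the simulation, most smaller changes would be missed. Array weights, added after seeing the data, called 92 higher and 286 lower from 65 to 100 days in the high-starch cultivar. In added comparisons of 30 with 100 days, 8 unigenes were higher and 5 lower at 100 days in the low-starch cultivar, and 0 passed in the high-starch cultivar (2559 at an unadjusted p under 0.05).

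The interaction asks whether the cultivars change differently with age. It called 0 unigenes from 30 to 65 days (1449 at an unadjusted limma p under 0.05) and 0 from 65 to 100 days (1544), against 1626 by chance. For a log2 interaction of 3, 20% were recovered in simulation by adjusted p alone. If as few unigenes differed as in the simulation, most differences of that size would be missed.

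A group of 6 abundant unigenes, singled out after their values were seen, took a varying share of the FPKM. All 6 were among the 25 unigenes with the highest single values and lay within 27 consecutive ID numbers. Their share in the high-starch cultivar was 1.07% ± 1.67 at 30 days, 5.30% ± 1.84 at 65 days and 9.99% ± 4.66 at 100 days (SD, n = 3 each). In the low-starch cultivar it was 0.26% ± 0.26, 1.92% ± 2.06 and 5.10% ± 3.18 (SD, n = 3 each). The high-starch mean at 30 days rests on 1 library (2.99%, against 0.20% and 0.015%), and low-starch replicate 3 had the lowest share of its group at 65 days (0.36%) and 100 days (1.44%). None of the 6 passed a comparison of successive ages. In the averaged cultivar comparison 3 of the 6 were higher in the high-starch cultivar by limma, and 2 were at 65 days.

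**Figure D4:**
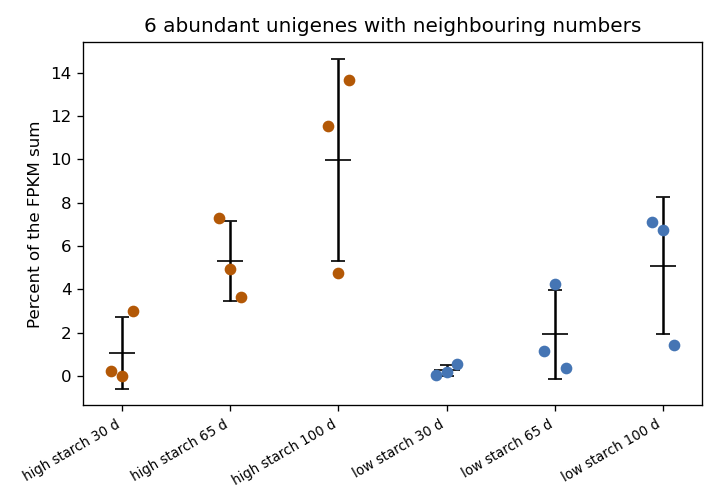
Share of the FPKM sum taken by 6 abundant unigenes with neighbouring ID numbers, in percent, per library; points are libraries, horizontal marks group means and bars SD (n = 3). Group means run from 0.26% in low-starch roots at 30 days to 9.99% in high-starch roots at 100 days.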

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

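Apart from the test of matched libraries, the tests here were chosen after the result was seen. For 28 measures and cultivars, each over 9 libraries, the gap of the extreme library was compared with Dixon's critical value of 0.493, a set of measures chosen after seeing the data. In 1 case a library lay far from the others: in low-starch 100 d replicate 3 the most abundant unigene took 12.5% of the FPKM. Chance alone gives about 1 in 20 such cases, so 1 of 28 is not more than chance would give. The gap of an extreme library shrinks where a second library is extreme too. The share of the 10 most abundant unigenes, 40.5% in low-starch 100 d replicate 3 and 25.8% in 65 d replicate 3, was not flagged. The count therefore does not show that no other library is apart.

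The first pattern is that unigenes of low abundance were more often higher in the high-starch cultivar, where 1 read was worth less FPKM, a sign of deeper libraries if the values were not scaled further. A test fixed before its result was seen compared libraries of matched depth at 65 days: among unigenes under 5 FPKM differing at least 2-fold, 49.9% were higher, against 63.9% with all 3 libraries per cultivar, as depth would predict; the single pairs ran from 44.7% to 55.1%, and 2 of these 4 use low-starch replicate 3, the library of the last pattern here. In the 3 of 27 pairs whose high-starch library had the larger 1-read value, 54.8% (30 days), 49.0% and 44.7% (65 days) were higher. The 65-day pairs are among the matched ones. At 100 days every high-starch library had the smaller 1-read value, and the shares ran from 64.0% to 71.1% without following the gap in depth. They were 71.0% at a log2 difference of -0.45 and 66.8% at -0.93. Pairs of 1 age share libraries, so these shares do not decide it. In a test added afterwards for the 3 ages together, with depth in a linear model, the cultivar term of the mean log2 level fell from 0.27 to 0.11 (SE 0.05) and stayed above 0 (permutation of residuals within age, p = 0.021, and 0.029 with age in the model), which argues against a linear effect of this depth measure as the whole cause. A first version of that test, which relabelled cultivars with depth fixed (exact permutation p = 0.00475), was dropped, since it breaks the link of depth with cultivar and called 14.4% of simulated cases without a cultivar effect, against 5.4% and 5.2% for its replacements. Depth and cultivar go together in these libraries, and the matched test rests on 4 libraries. How near these unigenes lie to the value of 1 read is unknown, since the absolute depth is. Depth may account for much of the pattern, and how much is open. An assembly built more from high-starch reads cannot be told apart from depth: 20 unigenes at 5 FPKM or more were listed at 0 in the low-starch cultivar and 23 in the high-starch cultivar, and a true cultivar difference also stays open.

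The second pattern is that no unigene passed the age comparisons. Whether uneven libraries within groups hid changes stays open: array weights gave 402 calls over the 4 comparisons. The weights ran from 0.35 to 3.88 and are themselves estimated from 3 libraries per group, so these calls are not evidence of which unigenes changed. An effect of age stays open, and not only a small one. In simulation, with few unigenes changed, 58% of log2 changes of 3 were recovered from 30 to 65 days in the high-starch cultivar.

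The last pattern is a set of unigenes far above the rest in low-starch 65 d replicate 3 and 100 d replicate 3, where the 10 most abundant unigenes took 25.8% and 40.5% of the FPKM, against 17.3% at most elsewhere. Whether 1 RNA source brought the set stays open. Ratios between its members were read in the 16 other libraries under 3 definitions of the set, and their spread was 1.71 (37 unigenes, the definition written first), 1.53 (24) and 0.40 (6, written after the others were known) times that of the set mean. These values leave it open, since under each definition the set held a much smaller share of the FPKM in those libraries: at most 1.16% against 7.26% and 11.98% in the 2 libraries (37 unigenes), 5.80% against 24.8% and 41.1% (24) and 5.32% against 21.6% and 37.5% (6). The 0.40 goes with 1 source, but for 6 unigenes picked after the other ratios were known. A wrong cultivar label was weighed with 2 tests: the first, that the lowest correlation with low-starch libraries exceeds the highest with high-starch ones, was missed by one library (difference -0.0316, 100 d replicate 3), while in a second, added after that, at least 82.6% of the unigenes called at 30 days lay nearer the low-starch mean in both, which argues against such a label; no biological explanation was tested.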

How the results depend on the processing

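Array weights, depth as a covariate, the omission of the 2 low-starch replicates 3 and of the 3 libraries apart on the second component, leaving out libraries for the separation and the zero listings, and separate fits for the sharing between ages were chosen after seeing the data. Of 332 values under other settings 281 kept their call or stayed within the limits for a count (1.5 times), as did 271 of 294 values with 1 library left out. The 281 include many age and interaction counts that stayed at 0. They also include the averaged fit of only the libraries compared, which is the main fit. The filters, the fit without a trend and the replicate block leave log2 differences unchanged. These shares therefore do not measure how robust the cultivar counts are. In the averaged comparison, the only one where they were followed, the 4 named unigenes kept direction and call throughout, but not their order. That of the 2 higher ones turned in 8 of 31 settings, with pseudocounts of 0.5 (Iba_33414 8.17, Iba_32651 7.92) and 0.1 (9.38 and 8.25) among them, and that of the 2 lower ones in 2, with depth as a covariate (Iba_34341 -8.31, Iba_24790 -7.92) and without the 2 low-starch replicates 3 (-8.42 and -8.13). The majority of calls turned from higher to lower in 4 cases: under quantile normalization at 30 days (1018 against 1030), at 100 days (1305 against 1495) and averaged (2692 against 2736), and with a filter at 5 FPKM at 100 days (987 against 1135).

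A filter at 5 FPKM, which tests fewer unigenes, gave 880, 1169, 987 and 2132 higher and 830, 989, 1135 and 1828 lower calls at 30, 65 and 100 days and averaged. Fits of only the libraries compared gave 483 higher and 409 lower at 30 days and 1043 and 762 at 65 days, but 2512 and 1720 at 100 days, and shared 366 higher and 292 lower calls between 30 and 65 days and 406 and 326 between 30 and 100 days. Depth as a covariate gave 831 and 459 at 30 days and 1122 and 801 at 100 days. Array weights gave 3403 and 2236 at 30 days and 5404 and 3686 at 100 days. Without the 2 low-starch replicates 3, higher calls were 1100 at 65 and 1009 at 100 days and lower calls 768 at 65 and 918 at 100 days. Zero listings at 5 FPKM were 20 and 23, and at 0.5 FPKM 325 in the low-starch cultivar. With unit variance cultivar took 21.9% of the variance. The cause was not tested.

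The age comparisons, with 0 calls, gave few under other settings (higher, then lower). Array weights gave 3 and 6 (low starch, 30 to 65 days), 92 and 286 (high starch, 65 to 100 days) and 9 and 6 (low starch, 65 to 100 days). No filter gave 13 and 4 (low starch, 30 to 65 days), 1 and 9 (low starch, 65 to 100 days), 1 higher (high starch, 30 to 65 days) and 1 lower (high starch, 65 to 100 days). Without the 3 libraries apart on the second component there were 18 and 44 (high starch, 65 to 100 days), 3 lower (low starch, 30 to 65 days) and 1 higher (low starch, 65 to 100 days). Without the 2 low-starch replicates 3 there was 1 higher (low starch, 30 to 65 days), 1 and 1 (low starch, 65 to 100 days), 1 lower (interaction, 30 to 65 days) and 1 higher (interaction, 65 to 100 days). From 30 to 65 days in low starch, quantile normalization gave 3 lower and a pseudocount of 0.1 gave 1 lower. Without an eBayes trend there was 1 lower (high starch, 65 to 100 days). The cause was not tested.

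With each library left out, higher and lower calls ranged over 934 to 1142 and 663 to 914 at 100 days and 1231 to 1988 and 775 to 1353 at 65 days, the lowest at 65 days without low-starch replicate 3. From 30 to 65 days they ranged over 0 to 13 and 0 to 2 (high starch, highest without 30 d replicate 3) and 0 to 22 and 0 to 18 (low starch, highest without 65 d and 30 d replicate 2). From 65 to 100 days they ranged over 0 to 4 lower (high starch, 4 without 65 d replicate 1) and 0 to 3 and 0 to 1 (low starch), and for the interaction from 30 to 65 days over 0 to 1 higher.

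Replicate numbers did not meet the limit for pairing, which every same-number pair must pass: 20 of 45 had a correlation of deviations over 0.1 (mean 0.070, against -0.035 for other numbers). A real link between libraries of 1 number could also miss so strict a limit, so missing it does not show that there is none. As a hint from the data, not the design, 10 of 18 libraries correlated best with their own number, where chance gives 6, the 3 libraries lowest on the second component are all replicate 1, and the 2 with the highest share in 10 unigenes are both replicate 3. A replicate block gave 3681 higher and 2432 lower averaged calls and moved no count by over 1.5 times. Gene list tests were not run, since no ID has a name. Absolute depth is unknown, which limits what a listed 0 shows.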

Other observations

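The count of other splits was planned, and the remaining tests here were chosen after the result was seen. Neighbouring ID numbers tended to have like profiles: over 24366 adjacent pairs of tested unigenes, 4.96% had a correlation across libraries over 0.8, against 0.60% for random partners and 1.14% for partners of like abundance. Unigenes called at only 1 age mostly had the same sign at both other ages, from 78.1% of those lower at 65 days only to 90.3% of those higher at 65 days only.

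The 6 abundant unigenes with neighbouring numbers held more of the FPKM at 100 than at 30 days in both cultivars. The mean log2 share was 5.44 higher in the high-starch and 4.52 higher in the low-starch cultivar, and with each library left out the differences ran from 3.55 (without high-starch 30 d replicate 2, whose share was 0.0153%) to 7.35 (without high-starch 30 d replicate 3, 2.99%) and from 3.69 to 5.33. Permuting ages within cultivar gave an exact two-sided p of 0.005, the smallest the 400 relabellings can give, but the unigenes were singled out and the trend was noticed in these same values, so the p does not support a change with age. Whether there is one stays open until other libraries are measured. The unigenes have no names here.

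Other splits of the libraries were counted for each comparison. For the averaged cultivar difference, 1 of 100 splits, the real one, gave as many calls (5964, highest other 1), and for the zero listings 1 of 100 (297, highest other 0). This is the smallest share that 100 splits can give. It makes a chance split of these libraries unlikely for both, provided that the libraries are independent, which the labels do not show. For single ages there are only 10 splits, too few for a share under 0.05: the real counts were 2326, 3323 and 2974 at 30, 65 and 100 days, and the highest others 153, 0 and 0. For the 4 age comparisons and the 2 interactions the real count was 0, which each of the 10 or 100 splits reaches by construction, so these counts say nothing about chance. The highest others were 283 and 0 in the high-starch and 11 and 26 in the low-starch cultivar. Those of the interactions were 3464 and 6764. A split that exchanges the cultivars at 1 age would move the cultivar difference into the interaction, but which splits gave these counts was not examined.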
